A study of Mus musculus with 352 samples.

How the data were processed

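Gene expression was measured by RNA sequencing in tibialis anterior muscle of 352 mice of strain C57BL/6. Per the labels, muscle was snap frozen at 6 zeitgeber times 4 h apart, RNA was isolated with Qiazol and the miRNeasy kit, and libraries were sequenced as 150 bp pairs on a NovaSeq with an average of 25 mega-read pairs (M). Per the series text, 360 samples were sequenced and 8 were excluded by the submitters for quality. The series text gives 2 males and 2 females per time point unless otherwise specified, and 3 to 5 mice per group and time point were present. Per the submitters' processing notes, reads were handled with FastQC 0.11.8, Trim Galore 0.5.0, HISAT2 2.1.0, featureCounts 1.6.2, edgeR 3.30.0 and limma 3.44.1 on the GRCm38 build. The deposited values are log2 FPKM by the authors, for 14413 genes, per the name of the deposited table. The lowest gene mean of -6.64 equals the log2 of 0.01, so 0.01 FPKM appears to have been added before the log. How the genes in the table were chosen is not given in the sources used here.

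The deposited values were checked before use. In 259 libraries, in the 47 Br-RE and RE-RE libraries of 10 weeks and in those of 26 weeks (46 libraries), each taken as a set, the means of females and males were equal in every gene to within 1e-05. Each Br-RE and RE-RE set also had the same mean in every gene as the other libraries of its age, 71 at 10 weeks and 140 at 26 weeks. These equalities point to a centring step that is not given in the sources used here. For that reason sexes were not compared, and RE-RE was also compared with Br-RE, which share a set. The size of a single read was read from the steps between low values of each library and the exon lengths of the annotation (GENCODE M21). It gave 14.8 to 47.8 M reads per library, with a median of 22.6 M, and group medians from 19.6 M in WT mice of 26 weeks to 24.8 M in Br-RE mice of 26 weeks. In the median library 93.9% of the low values lay within 0.1 of a whole read, and in the lowest 91.2%. At the median exon length of 4151 bp and the median depth, 1 FPKM corresponds to 93.7 reads. Libraries of a group correlated at r of 0.876 to 0.99, and no duplicates were found, with an SD of the difference of 0.254 for the closest pair.

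Analyses used R 4.3.3 with limma 3.58.1 and the data.table package at version 1.17.8, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes with a mean log2 value of at least 0 (1 FPKM) over all libraries were kept, 9862 in all. Symbols were present for 14339 genes, and 99.7% of the kept genes had an exon length. Linear models with moderated variance (limma, trend and robust options) held a level, a cosine and a sine of a 24 h period per group, and a term for sex. Rhythm in a group was an F test of cosine and sine in that group alone. Differences between groups were a two-sided moderated t test of the 24 h mean level and an F test of the cosine and sine differences, with the variance taken from the groups compared. Interactions were contrasts over 4 groups. P values were adjusted by the Benjamini-Hochberg method over the 9862 genes, with calls at 0.05, and counts at an unadjusted p under 0.05 are given beside counts of 0. Peak-to-trough folds were taken from the fitted amplitude, on which the error is a standard error (SE).

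Comparisons were KO against WT, each re-expressing genotype against KO and RE-RE against WT at 10 weeks, the interaction of muscle and brain re-expression at 10 weeks, KO against WT and each re-expressing genotype against KO at 26 weeks, old against WT mice of 26 weeks, TRF against ALF in WT, Mu-RE, KO and old mice, and the interaction of feeding with genotype in Mu-RE and KO mice. A knockout score per mouse was the mean log2 value of genes higher minus that of genes lower in KO than WT mice at 10 weeks, with adjusted p under 0.05 and a log2 difference of at least 0.5. An ageing score took its genes in the same way from old against WT mice of 10 weeks on ALF. Scores were compared with two-sided permutation tests of 1e+05 resamples within time points, adjusted by the Benjamini-Hochberg method over 8 tests per score, and the smallest possible p was 1e-05. These comparisons, the filter, the gene lists, the scores and the naming rule were fixed before the data were examined. RE-RE against Br-RE, the amplitude along the WT peak time with its 18 permutation tests, a gene length covariate and fits without 1 doubted library were added after the data were seen. The amplitude along the WT peak time is the projection of each gene's fitted rhythm on its peak time in WT mice at 10 weeks, averaged over 562 genes, and was not compared with the WT mice that set those times.

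Fixed gene lists covered the core clock (19 genes, 16 tested), glucose uptake and glycolysis (29, 28 tested), fatty acid oxidation and uptake (31, 28 tested), lipid synthesis (14, 12 tested), oxidative phosphorylation (30), atrophy and autophagy (21), glucocorticoid response (14), slow fibres (10, 8 tested), fast fibres (13), denervation and myogenic genes (15, 7 tested), extracellular matrix (22), inflammation and senescence (17, 7 tested), heat shock (15, 13 tested), antioxidant defence (16, 14 tested) and the mitochondrial genome (10). Markers of other cells covered macrophages and lymphoid cells (15, 9 tested), fibroblasts (8, 7 tested), endothelial and mural cells (12), adipocytes (8, 3 tested), nerve (8, 3 tested), tendon (7, 5 tested), red blood cells (6, 5 tested) and satellite cells (6, 3 tested). Each list was tested with camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists, and its members were counted with adjustment over all genes and over the list alone. Overlaps between rhythmic genes used a one-sided Fisher's exact test, with the expected number for independent lists.

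Genes named per level comparison were the 6 higher and 6 lower called genes of largest absolute log2 difference, with a mean log2 value of at least 1 (2 FPKM), the same sign in females and males, and no predicted gene model. Per rhythm count they were the 8 of largest amplitude and per rhythm comparison the 8 of smallest p, by the same filters, whose form for both sexes in rhythms was settled after the data were seen. Any core clock gene and up to 4 members of smallest p of each fixed list could also be named. Alternatives were no filter on low values, a pseudocount of 1 FPKM, quantile normalization, 1 fit over all 15 groups, time as a factor, the number in the sample label as a block, scores without the core clock list, and leaving out 1 animal of each time point in turn (4 alternatives). Those added later were the slope of expression on exon length of each library as a covariate and leaving out KO 26 week replicate 11 or WT 10 week replicate 1. Calls were compared with 100 splits of the same samples.

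The models were tested on simulated data with the spread of KO and WT mice at 10 weeks and of WT mice on TRF and ALF at 26 weeks, with 100 of 9862 genes changed per size. Recovery of a level difference of 0.5 log2 was 93% in both pairs. For rhythm it was 69% and 63% at 0.5 and 93% and 94% at 1. False calls were 8 to 11 per test, but 1 permuted split of real samples gave 3377. Core clock genes Npas2, Hlf and Ciart were below the filter. Exons, splice forms and the stop cassette were not analysed, as each gene had 1 value.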

Results

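Tibialis anterior, a fast-twitch muscle of the lower leg, was profiled by RNA sequencing in 352 mice in 15 groups of 22 to 25 animals. Each group was sampled at 6 zeitgeber times (ZT, hours after lights on), 4 h apart. Per the labels, the core clock gene Bmal1 (symbol Arntl) was intact in wild-type mice (WT), blocked by a floxed stop cassette (KO), or switched back on by Cre in skeletal muscle (Mu-RE), in brain (Br-RE) or in both (RE-RE). At 10 to 12 weeks of age, referred to as 10 weeks, there were 23 WT, 23 KO, 25 Mu-RE, 23 Br-RE and 24 RE-RE mice fed ad libitum (ALF). At 26 weeks there were 22 WT, 24 KO, 24 Mu-RE, 22 Br-RE and 24 RE-RE mice on ALF, and 24 WT, 23 Mu-RE and 23 KO mice on time-restricted feeding (TRF). Old wild-type mice of 85 to 116 weeks made up 24 on ALF and 24 on TRF. Groups named without a feeding schedule were on ALF. Estimated depth was 14.8 to 47.8 mega-reads per library (median 22.6). The comparisons ask which daily and steady-state transcripts of muscle depend on the clock of the muscle, of the brain or of both, and how feeding time and age bear on them. Counts below are out of 9862 genes, called by limma at a Benjamini-Hochberg adjusted p of 0.05, with two-sided tests of level.

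Arntl itself (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, GRCm38), which encodes the clock transcription factor BMAL1, cycled in WT muscle at 10 weeks and lost its rhythm in KO muscle. Its WT amplitude was 1.57 (SE 0.11, adjusted p = 6.36e-08), an 8.82-fold difference between trough and peak, with the peak at ZT 23. In KO muscle of that age the amplitude was 0.06 (SE 0.06) with no rhythm called (limma, unadjusted p = 0.601), and the difference in rhythm was called (adjusted p = 2.23e-10). The mean log2 level was 3.42 (SD 0.19, n = 23) in KO and 2.77 (SD 1.18, n = 23) in WT mice at 10 weeks, and 3.70 (SD 0.23, n = 24) and 2.59 (SD 0.90, n = 22) at 26 weeks. These values add up reads over the whole gene, so they do not show whether the stop cassette was present. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a direct target of BMAL1, gave a clearer reading of the genotypes. At 10 weeks its mean log2 level was 3.04 (SD 1.43, n = 23) in WT, 0.25 (SD 0.25, n = 23) in KO, 0.64 (SD 0.21, n = 23) in Br-RE, 2.90 (SD 0.86, n = 25) in Mu-RE and 3.47 (SD 1.18, n = 24) in RE-RE muscle. Ces1d (ENSMUSG00000056973, chromosome 8, 93166068 to 93197838), which encodes a carboxylesterase, was low in all 115 KO and Br-RE libraries (log2 of 0.0996 or below) and high in all 237 others (1.28 or above). By this gene 0 libraries were on the wrong side of that divide, which does not separate KO from Br-RE mice, nor WT, Mu-RE and RE-RE mice from each other.

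Loss of Bmal1 lowered Ces1d, Car3 and Dbp in young muscle and raised Mybph and Cdkn1a. Beside Ces1d, which fell by 6.02 on the log2 scale (SE 0.22, adjusted p = 3.6e-25), the lowest KO genes against WT at 10 weeks included Car3 (carbonic anhydrase 3), at -3.77 (SE 0.12). Zfp385a, a zinc finger gene, rose by 2.78 (SE 0.13). Dbp fell by 2.71 (SE 0.13, adjusted p = 1.28e-21), and Tbc1d1, which governs glucose transporter traffic, was at -2.41 (SE 0.12). Large increases were in Mybph, a myosin-binding protein, at 2.96 (SE 0.28, adjusted p = 7.52e-12), and in Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, at 2.64 (SE 0.23, adjusted p = 6.1e-13). Cilp, a matrix protein, rose by 2.66 (SE 0.19), and Dupd1, a phosphatase, by 2.65 (SE 0.11). In all, 1999 genes were higher and 2128 lower in KO muscle, of which 308 and 359 differed at least 1.5-fold.

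In the same comparison Nr1d2, Per3 and Hk2 fell and Clock, Plin5 and Fabp3 rose. Of 16 core clock genes, 4 rose and 11 fell (5 and 11 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.00077, adjusted p = 0.0646 with an estimated correlation). Nr1d2 and Per3, partners in the clock loop, were at -2.24 (SE 0.07) and -2.83 (SE 0.16), while Clock rose by 0.94 (SE 0.06). Of 28 glucose uptake and glycolysis genes, 6 rose and 12 fell (6 and 12 adjusted over the list alone). They included Hk2 (hexokinase 2) at -1.40 (SE 0.11) and the glucose transporter Slc2a4 at -0.53 (SE 0.06) (camera adjusted p = 0.0283, adjusted p = 0.473 with an estimated correlation). Fatty acid genes went the other way, in that 16 rose and 5 fell (17 and 5 adjusted over the list alone) of 28. Plin5 was at 1.24 (SE 0.14) and Fabp3 at 1.17 (SE 0.15) (camera adjusted p = 0.0152, adjusted p = 0.509 with an estimated correlation). Of 30 oxidative phosphorylation genes, 12 rose (12 adjusted over the list alone) (camera adjusted p = 0.00237, adjusted p = 0.509 with an estimated correlation). All 9 macrophage and lymphoid markers fell, C1qa by 1.21 (SE 0.20), with a median of -0.92 (camera adjusted p = 0.000594, adjusted p = 0.456 with an estimated correlation). Of 7 fibroblast markers, 5 fell (5 adjusted over the list alone) (camera adjusted p = 0.00258, adjusted p = 0.456 with an estimated correlation). Of 12 endothelial and mural markers, 7 rose and 1 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.0283, adjusted p = 0.509 with an estimated correlation). Fast fibre genes were mostly higher, since 8 rose and 2 fell (8 and 3 adjusted over the list alone) of 13, although Myh1 fell by 1.04 (SE 0.10), and of 8 slow fibre genes 1 rose and 2 fell (1 and 3 adjusted over the list alone).

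Among genes of the remaining lists, Glul fell in KO against WT muscle at 10 weeks. Of 14 glucocorticoid-responsive genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), with Glul (glutamine synthetase) at -1.36 (SE 0.16). Of 13 heat shock genes, 5 fell (4 adjusted over the list alone). WT 10 week replicate 1, at ZT 0, lay 1.48 above its group in these genes, and without it 1 rose and 4 fell. Of 7 inflammation and senescence genes, 5 rose (5 adjusted over the list alone). Atrophy and autophagy genes went both ways, in that 7 rose and 8 fell (7 and 8 adjusted over the list alone) of 21, and their median of -0.09 differed in sign from their mean of 0.06. Of 12 lipid synthesis genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone), and of 14 antioxidant genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone). Of 7 denervation and myogenic genes, 4 rose (5 adjusted over the list alone), and of 22 extracellular matrix genes, 5 rose and 1 fell (4 and 0 adjusted over the list alone). Among markers of other cells, Car3 fell and Fabp4 rose of 3 adipocyte genes, Mbp rose of 3 nerve genes, Cilp of 5 tendon genes and Sdc4 of 3 satellite cell genes. Of 10 genes of the mitochondrial genome, 6 fell (7 adjusted over the list alone) (camera adjusted p = 0.0199, adjusted p = 0.509 with an estimated correlation), which is uncertain because nuclear copies share their reads. Red blood cell genes were not called in either direction, with a median of 0.45 over 5 genes (camera adjusted p = 0.21, adjusted p = 0.611 with an estimated correlation).

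Core clock genes and Pdk4 cycled in young WT muscle. Dbp cycled 12.9-fold with a peak at ZT 10.2, Per2 with an amplitude of 1.73 (SE 0.14, adjusted p = 3.34e-07). Nr1d1, a repressor of Arntl, cycled 9.22-fold with a peak at ZT 5.23. Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), which shuts off glucose oxidation, cycled 6.91-fold with a peak at ZT 3.84 (adjusted p = 0.0185). The called rhythms of WT mice at 10 weeks numbered 576, with 2218 genes at an unadjusted p under 0.05, and 337 of them spanned at least 1.5-fold. They held 14 of 16 core clock genes (14 adjusted over the list alone), 7 of 28 fatty acid genes (9 adjusted over the list alone), 3 of 28 glycolysis genes (4 adjusted over the list alone) and 6 of 14 glucocorticoid-responsive genes (11 adjusted over the list alone). The count was 184 to 278 when 1 animal per time point was left out in turn. In KO muscle 7 genes were called rhythmic, with 338 at an unadjusted p under 0.05. Among those 7 was Cebpb, a transcription factor, with an amplitude of 1.16 (SE 0.18, adjusted p = 0.0213) and a peak at ZT 15.1. A difference in rhythm between KO and WT was called for 51 genes, led by Arntl and Dbp (adjusted p = 4.95e-08) and including Nr1d1 (adjusted p = 0.000467) and Tef (adjusted p = 0.00201), and 10 of the 16 core clock genes were among them.

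**Figure D1:**
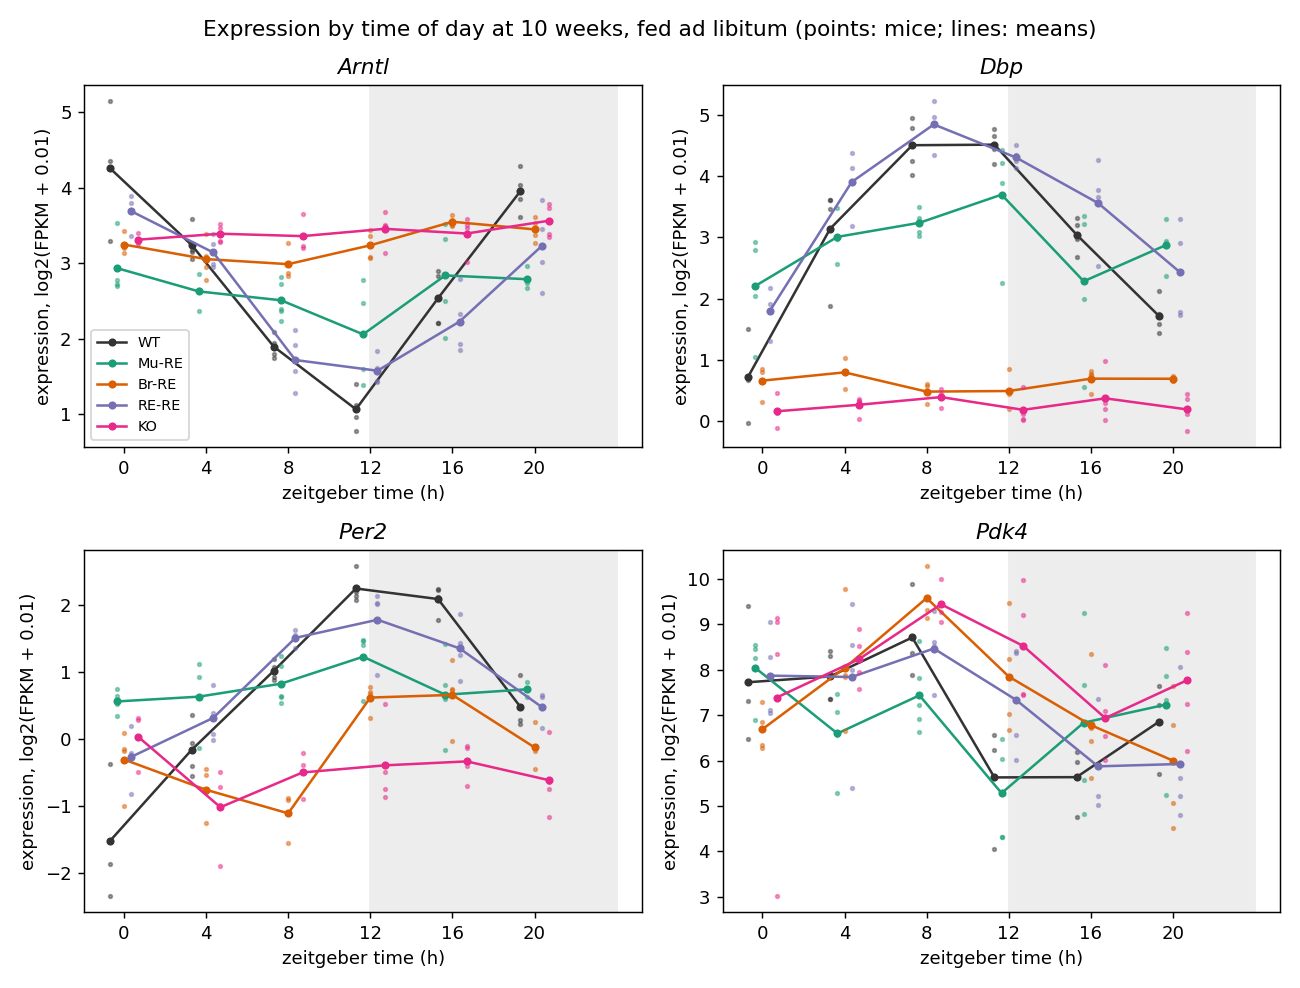
Log2 levels of Arntl, Dbp, Per2 and Pdk4 by zeitgeber time (hours) in the 5 genotypes at 10 weeks, with a point per mouse, lines through the means and grey for ZT 12 to 24. Arntl cycled in WT (amplitude 1.57) and RE-RE (amplitude 1.12) muscle and was flat in KO muscle (amplitude 0.06). Dbp had a mean of 0.25 in KO, 0.64 in Br-RE and 3.04 in WT muscle.

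Switching Bmal1 on in muscle alone raised the level of clock targets at 10 weeks, while no rhythm of a core clock gene was called. Against KO muscle, Mu-RE muscle was higher in Ces1d by 6.93 (SE 0.20, adjusted p = 4.96e-30), in Car3 by 3.99 (SE 0.12), in Mylk4 (a myosin light chain kinase) by 3.24 (SE 0.17) and in Dbp by 2.63 (SE 0.17). Dupd1 was at -3.17 (SE 0.10), Olfm1, a secreted protein, at -2.90 (SE 0.09), and Cdkn1a fell by 2.39 (SE 0.18, adjusted p = 9.29e-15). In all, 1716 genes were higher and 1694 lower. Of 16 core clock genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone). Their median was 0.78 (camera adjusted p = 0.00033, adjusted p = 0.00812 with an estimated correlation). Fatty acid genes mostly fell, in that 3 rose and 16 fell (4 and 17 adjusted over the list alone) of 28, with a median of -0.30 (camera adjusted p = 0.00156, adjusted p = 0.839 with an estimated correlation), and Plin5 at -1.22 (SE 0.16). Of 30 oxidative phosphorylation genes, 12 fell (14 adjusted over the list alone) (camera adjusted p = 0.00033, adjusted p = 0.839 with an estimated correlation). Of 28 glycolysis genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone), with Tbc1d1 at 1.61 (SE 0.10) (camera adjusted p = 0.31, adjusted p = 0.839 with an estimated correlation). The rhythms called in Mu-RE muscle numbered 7, with 1297 genes at an unadjusted p under 0.05, and limma called none of the 16 core clock genes. Arntl had an amplitude of 0.33 (SE 0.12) and Dbp of 0.53 (SE 0.23), with adjusted p = 0.378 and 0.428. Cebpb was rhythmic in Mu-RE muscle too, with an amplitude of 1.15 (SE 0.10, adjusted p = 1.78e-06), and 4 of the 7 genes were also among the 7 of KO muscle. A difference in rhythm from KO mice was called by limma for 0 genes, with 266 at an unadjusted p under 0.05.

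With Bmal1 on in brain alone, Pdk4, Ucp3 and Fkbp5 cycled in young muscle, while Dbp was not called rhythmic. In Br-RE muscle at 10 weeks Pdk4 cycled 9.07-fold with a peak at ZT 7.93, and Ucp3, a mitochondrial carrier induced by fatty acids, 4.4-fold with a peak at ZT 7.9. Arrdc2, an arrestin-domain gene, cycled 12.8-fold and Fkbp5, a glucocorticoid target, 5.22-fold with a peak at ZT 16.6. A difference in rhythm from KO mice was not called for Pdk4, Ucp3 or Fkbp5 (limma, adjusted p = 0.671, 0.749 and 0.21), and in KO muscle Pdk4 had an amplitude of 0.94 (SE 0.44, not called). Arntl had a small amplitude of 0.27 (SE 0.05, adjusted p = 0.00358) with its peak at ZT 17.9 rather than ZT 23. The called rhythms numbered 2862, with 4296 at an unadjusted p under 0.05. Gene length bears on this count, since 164 were called when the length slope of each library was a covariate, 146 of them also called without it. Pdk4, Ucp3, Fkbp5, Glul and Per2 were still called in that fit and Arntl and Arrdc2 were not. The 2862 held 19 of 28 fatty acid genes (23 adjusted over the list alone), 16 of 28 glycolysis genes (17 adjusted over the list alone), 11 of 14 glucocorticoid-responsive genes (12 adjusted over the list alone) and 8 of 16 core clock genes (11 adjusted over the list alone). With the length covariate the called genes of these 4 lists were 5, 5, 5 and 4. With WT mice of 10 weeks 194 rhythmic genes were shared, where 167 were expected for independent lists (Fisher's exact test, p = 0.00686), and their peaks lay a median of 3.34 h apart.

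In level, limma called 20 genes higher and 31 lower in Br-RE than in KO muscle at 10 weeks. Mylk4 rose by 0.74 (SE 0.18, adjusted p = 0.0479), Tbc1d1 by 0.62 (SE 0.12), Nr1d2 by 0.47 (SE 0.07, adjusted p = 0.000227) and Nr1d1 by 0.55 (SE 0.13), while Zfp385a was at -0.60 (SE 0.13) and Dupd1 at -0.53 (SE 0.09). Of 16 core clock genes, 5 rose (6 rose and 2 fell adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.000274, adjusted p = 0.0165 with an estimated correlation). Endothelial and mural markers had a median of -0.22 (camera adjusted p = 3.02e-09, adjusted p = 0.119 with an estimated correlation). In the values, the Br-RE and RE-RE libraries of each age together had the mean of the other libraries of that age in every gene. This points to centring. Levels of these groups against KO or WT mice would partly reflect that step, while rhythms and RE-RE against Br-RE would not. A difference in rhythm from KO mice was called for 90 genes, the smallest p belonging to Man1b1, an enzyme of glycan trimming, and Vcl, the adhesion protein vinculin (both adjusted p = 0.0151), but for 0 genes with the length slope as a covariate. The count of genes differing in level was 3 to 44 and that of rhythm 0 to 310 when 1 animal per time point was left out in turn.

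With Bmal1 on in brain and muscle together, the muscle clock cycled again at 10 weeks. In RE-RE muscle Arntl had an amplitude of 1.12 (SE 0.10, adjusted p = 1.1e-06) and a peak at ZT 23.4, Dbp cycled 7.23-fold with a peak at ZT 9.73, and Nr1d1 6.22-fold with a peak at ZT 4.33. The called rhythms numbered 58, with 649 at an unadjusted p under 0.05, and held 7 of 16 core clock genes (13 adjusted over the list alone). Of the 58, 46 were also rhythmic in WT mice, where 3.39 were expected for independent lists (Fisher's exact test, p = 1.47e-46), with peaks a median of 0.718 h apart. Rhythm differed from KO mice in 15 genes, including Arntl (adjusted p = 5.18e-08), Dbp (adjusted p = 8.96e-05) and Pnpla3, a lipase (adjusted p = 0.00108). Rhythm also differed from Br-RE mice in 15 genes, again including Arntl (adjusted p = 3.23e-08), Dbp (adjusted p = 3.1e-06) and Nr1d1 (adjusted p = 0.000154). Against WT mice limma called a difference in rhythm for 0 genes, with 341 at an unadjusted p under 0.05.

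In level, RE-RE muscle at 10 weeks had high clock output and Ces1d and low Cdkn1a. Against Br-RE mice, which belong to the same set of libraries, 1460 genes were higher and 1715 lower, with Ces1d at 7.06 (SE 0.18, adjusted p = 9.8e-32), Car3 at 4.55 (SE 0.17) and Dbp at 2.84 (SE 0.13), and with Dupd1 at -2.82 (SE 0.08) and Cdkn1a at -2.13 (SE 0.19). Of 16 core clock genes, 10 rose and 4 fell (10 and 5 adjusted over the list alone) (camera adjusted p = 0.00014, adjusted p = 0.0416 with an estimated correlation), and of 30 oxidative phosphorylation genes, 24 fell (26 adjusted over the list alone) (camera adjusted p = 1.14e-09, adjusted p = 0.221 with an estimated correlation). Against KO mice 1637 genes were higher and 1586 lower, with Ces1d at 7.86 (SE 0.21) and Cdkn1a at -2.75 (SE 0.23). Against WT mice 207 were higher and 195 lower, and centring bears on both to an unknown extent. Ces1d rose above WT by 1.84 (SE 0.12, adjusted p = 1.24e-14) and Car3 by 1.08 (SE 0.13), while Csrp3, a muscle stress sensor, was at -1.61 (SE 0.34) and Atf3, a stress-induced transcription factor, at -1.66 (SE 0.41). Macrophage markers had a median of -0.52 against WT (camera adjusted p = 5.5e-08, adjusted p = 0.2 with an estimated correlation) and fibroblast markers of -0.49 (camera adjusted p = 3.89e-08, adjusted p = 0.0844 with an estimated correlation).

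Whether brain and muscle clocks act more than additively was tested directly from the 4 groups KO, Mu-RE, Br-RE and RE-RE at 10 weeks. The interaction in rhythm was called for Nr1d1 (adjusted p = 0.00249) and Leo1, a transcription elongation factor (adjusted p = 0.0061), with 1453 genes at an unadjusted p under 0.05. The interaction in level was called for Cyyr1, a membrane protein, at 0.56 (SE 0.11, adjusted p = 0.0244), and for Nctc1, a muscle long non-coding RNA, at -0.42 (SE 0.09, adjusted p = 0.0445), with 984 genes at an unadjusted p under 0.05. Cyyr1 falls outside the naming rule and was chosen after its values were seen. All 4 calls were lost with the length slope of each library as a covariate, and the counts were 0 to 126 in rhythm and 0 to 44 in level with 1 animal per time point left out. Endothelial and mural markers had a median interaction of 0.34 (camera adjusted p = 8.69e-11, adjusted p = 0.0722 with an estimated correlation).

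A measure that does not count calls gave how much of the WT daily program was left in each genotype at its WT peak times. Shifted rhythms enter this measure only in part, and those of other genes not at all. It is the amplitude along the WT peak time, averaged over 562 genes rhythmic in WT mice at 10 weeks and outside the core clock list, and its 18 tests were permutation tests within time points, two-sided, with Benjamini-Hochberg adjustment. At 10 weeks it was 0.08 on the log2 scale (SE 0.02, n = 23) in KO, 0.06 (SE 0.02, n = 25) in Mu-RE, 0.09 (SE 0.01, n = 23) in Br-RE and 0.18 (SE 0.02, n = 24) in RE-RE muscle. RE-RE exceeded KO mice by 0.11 (SE 0.03, p = 0.00014, adjusted p = 0.000504) and Br-RE mice by 0.09 (SE 0.02, p = 0.00047, adjusted p = 0.00121). Mu-RE and Br-RE mice did not differ detectably from KO mice (p = 0.416 and 0.461), but with the length slope as a covariate Br-RE mice exceeded them by 0.05 (p = 0.0345). The joint effect exceeded the sum of the single ones by 0.11 (SE 0.03, p = 0.00156, adjusted p = 0.00351), and by 0.06 with the length slope as a covariate (p = 0.0773). At 26 weeks the excess was 0.07 (SE 0.04, p = 0.128, adjusted p = 0.192), and 0.08 with that covariate (p = 0.0451).

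**Figure D2:**
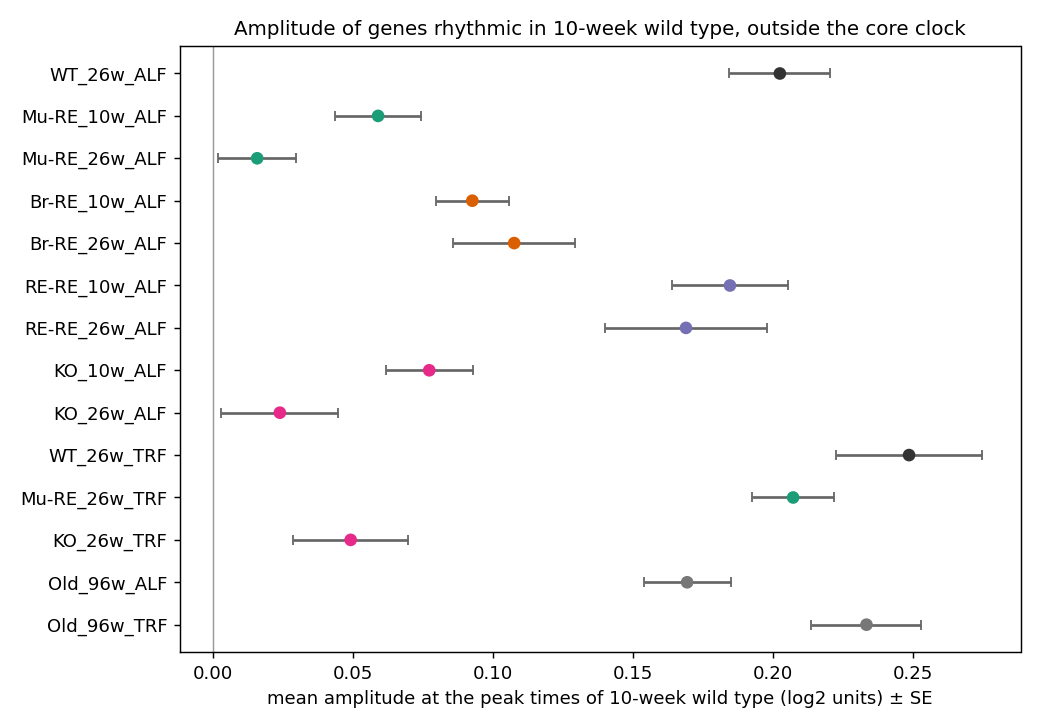
Mean amplitude (log2) along the WT peak time over 562 genes rhythmic in WT mice at 10 weeks, in the 14 other groups, with bars for the SE. RE-RE muscle at 10 weeks lay at 0.18 and KO, Mu-RE and Br-RE muscle at 0.09 or below, and Mu-RE muscle at 26 weeks moved from 0.02 on ALF to 0.21 on TRF.

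At 26 weeks KO muscle had low clock output and high Cilp and Cdkn1a. Against WT mice of that age Cilp (ENSMUSG00000042254, chromosome 9, 65265180 to 65280605) rose by 5.12 (SE 0.18, adjusted p = 7.36e-26), Cdkn1a by 4.45 (SE 0.22, adjusted p = 1.38e-20), and Cpne2, a calcium-dependent membrane protein, by 3.54 (SE 0.17). Ces1d was at -6.88 (SE 0.30), Mylk4 at -4.71 (SE 0.23) and Dbp at -3.13 (SE 0.11). In all, 2406 genes were higher and 2165 lower. Of 8 slow fibre genes, 4 rose (4 adjusted over the list alone), with Casq2 at 1.77 (SE 0.12) and Myl2 at 1.55 (SE 0.22) (camera adjusted p = 0.0444, adjusted p = 0.51 with an estimated correlation). Of 7 denervation and myogenic genes, 5 rose (5 adjusted over the list alone), with Myog at 1.91 (SE 0.15) (camera adjusted p = 0.00968, adjusted p = 0.19 with an estimated correlation). Of 28 fatty acid genes, 16 rose and 3 fell (18 and 3 adjusted over the list alone) (camera adjusted p = 0.00252, adjusted p = 0.51 with an estimated correlation). Of 12 lipid synthesis genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with Fasn at 1.61 (SE 0.18) (camera adjusted p = 0.0375, adjusted p = 0.335 with an estimated correlation). Of 12 endothelial markers, 10 rose (10 adjusted over the list alone) (camera adjusted p = 0.00964, adjusted p = 0.51 with an estimated correlation). Of 7 fibroblast markers, 6 fell (6 adjusted over the list alone) (camera adjusted p = 1.21e-05, adjusted p = 0.19 with an estimated correlation). Of 16 core clock genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone) (camera adjusted p = 0.00346, adjusted p = 0.19 with an estimated correlation). Rhythm was called for 103 genes in WT mice, including 9 of 16 core clock genes (13 adjusted over the list alone), and for 0 in KO mice (limma), with 705 and 596 at an unadjusted p under 0.05. Rhythm differed between KO and WT in 17 genes, led by Dbp (adjusted p = 5.97e-08) and Arntl (adjusted p = 8.74e-05), with 1 to 26 called when 1 animal per time point was left out, 4 with time as a factor and 32 without KO 26 week replicate 11, a library far above the others in glucocorticoid-responsive genes.

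Muscle Bmal1 raised Ces1d and Mylk4 and lowered Cilp and Cdkn1a at 26 weeks, and the last 3 of these differed from KO mice in the same directions in Br-RE muscle, where the share of centring is unknown. In Mu-RE against KO mice Ces1d rose by 6.34 (SE 0.28, adjusted p = 4.6e-23) and Mylk4 by 4.37 (SE 0.21), while Sln (sarcolipin, a calcium pump regulator) was at -3.34 (SE 0.28), Cdkn1a at -3.11 (SE 0.21) and Cilp at -2.80 (SE 0.19), with 1706 genes higher and 1635 lower. Of 7 denervation and myogenic genes, 5 fell (5 adjusted over the list alone), with Myog at -1.36 (SE 0.17) (camera adjusted p = 0.00624, adjusted p = 0.199 with an estimated correlation). In Br-RE against KO mice, 53 genes were higher and 58 lower, a share of 47.7% higher that became 58.1% with quantile normalization, and 15 to 122 differed with 1 animal per time point left out. Cilp was at -1.06 (SE 0.15, adjusted p = 6.33e-05), Cdkn1a at -0.94 (SE 0.18, adjusted p = 0.00282) and Ankrd1, a muscle stress gene, at -0.93 (SE 0.20), while Mylk4 rose by 0.96 (SE 0.26, adjusted p = 0.0466) and Fbp2, an enzyme of glycogen synthesis, by 0.67 (SE 0.13). Of 16 core clock genes, 6 rose and 1 fell (6 and 3 adjusted over the list alone), with Tef at 0.30 (SE 0.05) (camera adjusted p = 0.00628, adjusted p = 0.269 with an estimated correlation). In RE-RE against KO mice 1777 genes were higher and 1976 lower, with Ces1d at 8.22 (SE 0.24), Cilp at -4.52 (SE 0.21) and Sln at -3.85 (SE 0.34). The share of centring in the Br-RE and RE-RE levels against KO mice is unknown. Against Br-RE mice, RE-RE muscle had 1623 genes higher and 1859 lower, with Ces1d at 7.79 (SE 0.29), Cilp at -3.46 (SE 0.23) and 16 core clock genes of which 10 rose and 4 fell (11 and 4 adjusted over the list alone) (camera adjusted p = 0.000142, adjusted p = 0.000763 with an estimated correlation).

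At 26 weeks on ALF, Nr1d1 and Dbp cycled in RE-RE muscle, and Pdk4, Ucp3 and Per1 in Br-RE muscle. RE-RE muscle had 75 rhythmic genes (19 to 44 with 1 animal per time point left out) and 8 of 16 core clock genes (13 adjusted over the list alone), with Nr1d1 at 7.74-fold, Dbp at 5.38-fold and Glul among the larger ones. Of the 75, 48 were shared with WT mice of 10 weeks, where 4.38 were expected for independent lists (Fisher's exact test, p = 3.92e-41). Br-RE muscle had 68 (5 to 74 in those fits), with Pdk4 cycling 11.5-fold at ZT 8.87, Ucp3 4.97-fold and Per1 5.19-fold, and held 2 of 16 core clock genes (6 adjusted over the list alone) and 3 of 28 fatty acid genes (7 adjusted over the list alone). Limma called 0 in Mu-RE muscle, with 1253 at an unadjusted p under 0.05. RE-RE differed from Br-RE mice in the rhythm of 9 genes, including Arntl (adjusted p = 2.37e-05) and Dbp (adjusted p = 0.000191). Along the WT peak time the mean amplitude was 0.20 (SE 0.02, n = 22) in WT, 0.02 (SE 0.02, n = 24) in KO, 0.02 (SE 0.01, n = 24) in Mu-RE, 0.11 (SE 0.02, n = 22) in Br-RE and 0.17 (SE 0.03, n = 24) in RE-RE muscle. Br-RE exceeded KO mice by 0.08 (SE 0.03, permutation p = 0.00699, adjusted p = 0.014; p = 0.0509 in 1 of 4 fits with 1 animal per time point left out) and RE-RE exceeded KO mice by 0.15 (SE 0.04, permutation p = 0.00034, adjusted p = 0.00102). RE-RE did not differ detectably from Br-RE mice (0.06, SE 0.04, permutation p = 0.101).

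A score of the young knockout state, read in mice that had no part in choosing its genes, placed the 26 week genotypes between KO and WT. It is the mean log2 level of 404 genes higher minus that of 456 genes lower in KO than WT mice at 10 weeks. Its mean was -0.77 (SD 0.22, n = 22) in WT, 0.87 (SD 0.18, n = 24) in KO, -0.27 (SD 0.14, n = 24) in Mu-RE, 0.64 (SD 0.12, n = 22) in Br-RE and -0.56 (SD 0.14, n = 24) in RE-RE muscle. Tests on 2 scores came to 16 permutation tests within time points, two-sided, whose smallest possible p was 1e-05. Mu-RE fell by 1.13 from KO mice (SE 0.04, p = 1e-05), Br-RE fell by 0.23 (SE 0.05, p = 8e-05, adjusted p = 0.000128), and RE-RE fell by 1.42 (SE 0.04, p = 1e-05), and the share of centring in the last 2 is unknown. RE-RE fell by 1.19 from Br-RE mice, which belong to the same set (SE 0.04, p = 1e-05).

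**Figure D3:**
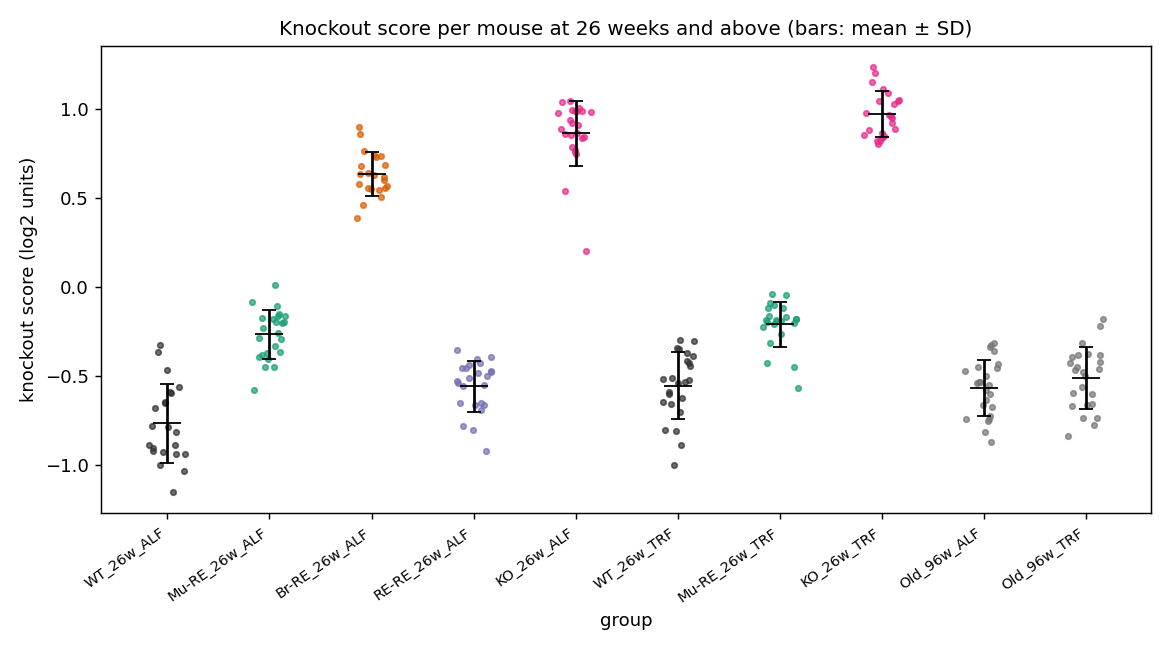
Knockout score (log2 units) of each mouse in the groups of 26 weeks and older, with a point per mouse and bars for the mean and SD. KO mice had a mean of 0.87 and Br-RE mice of 0.64, while Mu-RE (-0.27), RE-RE (-0.56) and WT (-0.77) mice lay below 0.

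Old wild-type muscle had a cycling clock and fewer matrix transcripts against WT mice of 26 weeks on ALF. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the main collagen of connective tissue, fell by 2.47 (SE 0.26, adjusted p = 7.42e-09), Postn was at -2.71 (SE 0.30), and all 22 of 22 extracellular matrix genes fell (22 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 4.92e-24, adjusted p = 0.109 with an estimated correlation). Ibsp, at -4.17 (SE 0.71), and Mmp13, at -3.89 (SE 0.71), both markers of bone, fell with them, and 9 of the 22 matrix genes were still called lower with a bone marker mean as a covariate. Mss51, a mitochondrial regulator of fast fibres, rose by 2.07 (SE 0.17, adjusted p = 1.7e-11), Rrad, a stress-induced GTPase, by 1.87 (SE 0.45) and Ostn (osteocrin, a muscle hormone) by 1.64 (SE 0.18). In all, 1277 genes were higher and 1106 lower, and 1040 to 3019 differed when 1 animal per time point was left out in turn. Of 21 atrophy and autophagy genes, 7 rose (7 adjusted over the list alone), with Cdkn1a at 1.03 (SE 0.17) and Fbxo32, a ubiquitin ligase of atrophy, at 0.41 (SE 0.12) (camera adjusted p = 0.00128, adjusted p = 0.489 with an estimated correlation). Of 7 denervation genes, 4 rose (4 adjusted over the list alone), with Musk at 0.58 (SE 0.14) and Myog at 0.70 (SE 0.17) (camera adjusted p = 0.0361, adjusted p = 0.489 with an estimated correlation). Of 30 oxidative phosphorylation genes, 10 fell (12 adjusted over the list alone) (camera adjusted p = 0.00107, adjusted p = 0.662 with an estimated correlation). Of 14 glucocorticoid-responsive genes, 4 rose (4 adjusted over the list alone) (camera adjusted p = 0.0228, adjusted p = 0.512 with an estimated correlation). Old muscle had 139 rhythmic genes, with Dbp cycling 12-fold and Arntl 4.61-fold, and 11 of 16 core clock genes (13 adjusted over the list alone). Limma called a difference in rhythm from WT mice of 26 weeks for 0 genes, with 109 at an unadjusted p under 0.05.

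An ageing score was the mean log2 level of 334 genes higher minus that of 428 lower in old than WT mice of 10 weeks. It showed no called difference between KO and WT mice at 26 weeks (-0.06, SE 0.09, permutation p = 0.492). Its mean was 0.53 (SD 0.25, n = 22) in WT, 0.47 (SD 0.32, n = 24) in KO, 0.61 (SD 0.26, n = 24) in Mu-RE, 0.53 (SD 0.20, n = 22) in Br-RE and 0.69 (SD 0.28, n = 24) in RE-RE muscle. RE-RE differed from KO mice by 0.23 (SE 0.09, permutation p = 0.0139, adjusted p = 0.0557, not called). TRF raised it in Mu-RE mice by 0.33 (SE 0.07, permutation p = 0.00028, adjusted p = 0.00224), from 0.61 to 0.91 (SD 0.30, n = 23). In WT and KO mice the change on TRF was not called (permutation p = 0.507 and 0.0913). The bone marker mean, lower in old mice, was 1.41 (SD 1.66) in WT and 0.96 (SD 1.05) in KO mice at 26 weeks. It went from 2.00 (SD 0.91) to 1.56 (SD 1.52) in Mu-RE mice. No score difference was tested without that tissue.

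Time-restricted feeding raised lipid synthesis genes in wild-type muscle at 26 weeks, and more genes were called rhythmic on it. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), a fatty acid desaturase, rose by 1.55 (SE 0.29, adjusted p = 0.000106), Fasn (fatty acid synthase) by 1.24 (SE 0.18), Srebf1, their regulator, by 0.59 (SE 0.09) and Cebpb by 1.25 (SE 0.16). Of 12 lipid synthesis genes, 9 rose (9 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 3.31e-05, adjusted p = 0.0415 with an estimated correlation). Of 28 fatty acid genes, 8 rose (8 adjusted over the list alone) (camera adjusted p = 0.0211, adjusted p = 0.727 with an estimated correlation). Of 12 endothelial and mural markers, 9 rose (10 adjusted over the list alone), with Egfl7 at 0.70 (SE 0.11) (camera adjusted p = 0.000518, adjusted p = 0.727 with an estimated correlation). Genes of the mitochondrial genome fell, 10 of 10 (10 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 5.11e-08, adjusted p = 0.447 with an estimated correlation), which nuclear copies make uncertain. Of 30 oxidative phosphorylation genes 1 rose and 12 fell (1 and 12 adjusted over the list alone) and the median was -0.07, but it was 0.06 with quantile normalization, where 11 rose and 9 fell. In all, 2065 genes were higher and 1978 lower. Rhythm was called for 3732 genes on TRF, with 4684 at an unadjusted p under 0.05, against 103 on ALF, and a difference in rhythm was called for 387, among them Klf13, a transcription factor (adjusted p = 0.00806). That last count was 0 to 540 when 1 animal per time point was left out in turn and 22 with time as a factor. Nearly all of these differences in rhythm were no longer called with the label number as a block. Along the WT peak time the gain in mean amplitude was 0.05 and was not called (SE 0.03, permutation p = 0.146, adjusted p = 0.203). Dbp cycled 15.1-fold, Pdk4 12.1-fold with a peak at ZT 9.92, and Ucp3 8.6-fold. The rhythms held 15 of 16 core clock genes (15 adjusted over the list alone), 20 of 28 fatty acid genes (24 adjusted over the list alone) and 13 of 28 glycolysis genes (14 adjusted over the list alone). The knockout score rose by 0.22 (SE 0.05, permutation p = 3e-05, adjusted p = 6e-05), from -0.77 to -0.55 (SD 0.19, n = 24).

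In mice with Bmal1 in muscle alone, core clock genes were rhythmic across the group on time-restricted feeding. Each mouse was sampled at a single time, so a flat group does not show that the clock of each mouse had stopped. On TRF Arntl cycled in Mu-RE muscle with an amplitude of 1.15 (SE 0.10, adjusted p = 3.27e-06) and a peak at ZT 22.2, against 0.10 (SE 0.11) on ALF, and the difference was called (adjusted p = 0.000136). Nr1d1 cycled 7.7-fold with a peak at ZT 3.25, Dbp 6.42-fold at ZT 7.77, Pdk4 18.7-fold at ZT 10.9 and Ucp3 9.94-fold. Rhythm was called for 687 genes (134 to 529 with 1 animal per time point left out), with 2307 at an unadjusted p under 0.05, and held 11 of 16 core clock genes (12 adjusted over the list alone), 5 of 28 fatty acid genes (5 adjusted over the list alone) and 4 of 14 glucocorticoid-responsive genes (4 adjusted over the list alone). Of these, 166 were shared with WT mice of 10 weeks, where 40.1 were expected for independent lists (Fisher's exact test, p = 7.85e-63). Rhythm differed between feeding schedules in 479 genes, among them Slc25a36, a mitochondrial carrier (adjusted p = 8.87e-05), Hsp90aa1, a chaperone (adjusted p = 0.000136) and 6 of 16 core clock genes. That count was 20 to 1307 when 1 animal per time point was left out in turn and 2441 with time as a factor. It was lower with the label number as a block. Along the WT peak time the mean amplitude rose by 0.19 (SE 0.02, permutation p = 1e-05, adjusted p = 6e-05), to 0.21 (SE 0.01, n = 23). In level, 893 genes were higher and 776 lower, 594 in all with the length slope as a covariate and 275 to 1142 with 1 animal per time point left out. Fbp2 rose by 0.77 (SE 0.15, adjusted p = 0.000751), Rbm3, a cold-induced RNA-binding protein, by 0.81 (SE 0.10) and Cebpb by 0.97 (SE 0.22). Of 28 fatty acid genes, 7 rose (8 adjusted over the list alone) (camera adjusted p = 0.000797, adjusted p = 0.782 with an estimated correlation). Of 30 oxidative phosphorylation genes, 7 rose (12 adjusted over the list alone) (camera adjusted p = 0.000797, adjusted p = 0.782 with an estimated correlation).

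In KO muscle on the same feeding schedule no rhythm of Arntl or Dbp was called. On TRF Arntl had an amplitude of 0.18 (SE 0.06, limma, adjusted p = 0.109) and Dbp of 0.17 (SE 0.08, adjusted p = 0.274), while Nr1d1 cycled with an amplitude of 0.58 (SE 0.12, adjusted p = 0.0269) and Per3 of 0.57 (SE 0.09, adjusted p = 0.0114). Rhythm was called for 611 genes on TRF, with 3216 at an unadjusted p under 0.05, and for 1 to 75 when 1 animal per time point was left out in turn. They included Tnfrsf12a, a muscle stress receptor, at 6.6-fold, Txnip, an inhibitor of glucose uptake, at 2.76-fold, and 5 of 16 core clock genes (5 adjusted over the list alone). Limma called a difference in rhythm between feeding schedules for 0 genes, with 869 at an unadjusted p under 0.05. In 1 fit over all groups such differences were called, so the 0 depends on the fit. In level 471 genes were higher and 925 lower, a share of 33.7% higher that became 47.4% with quantile normalization. The 1396 were 90 to 1504 with 1 animal per time point left out and 2749 in 1 fit over all groups. Cebpb rose by 1.23 (SE 0.20, adjusted p = 0.000123) and Postn by 1.01 (SE 0.34), and 4 of 22 matrix genes rose (4 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.00143, adjusted p = 0.933 with an estimated correlation). The mean of the bone markers rose beside them, from 0.96 (SD 1.05, n = 24) on ALF to 1.99 (SD 1.26, n = 23) on TRF. The knockout score rose by 0.11 (SE 0.04, permutation p = 0.0154, adjusted p = 0.0206), and by 0.07 with no filter on low values (permutation p = 0.198).

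The response to feeding time differed between Mu-RE and KO mice when the difference itself was tested. In the amplitude along the WT peak time, the gain on TRF was 0.17 larger in Mu-RE than in KO mice (SE 0.04, permutation p = 0.00014, adjusted p = 0.000504). The interaction in rhythm was called for Arntl (adjusted p = 0.0243) and D10Wsu102e (adjusted p = 0.013), with 760 genes at an unadjusted p under 0.05. That in level was called for 6 genes, all with a more positive response in Mu-RE mice, for 3 without KO 26 week replicate 11, and for 0 to 3 with 1 animal per time point left out. They were Pdcd4, a translation repressor, at 0.44 (SE 0.08, adjusted p = 0.0076), Olfm1 at 0.74 (SE 0.15, adjusted p = 0.0157), Mrps30, Dst, 2810402E24Rik and 1 gene without a symbol, with 1252 genes at an unadjusted p under 0.05. D10Wsu102e, Dst, 2810402E24Rik and the gene without a symbol fall outside the naming rule and were chosen after their values were seen.

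**Figure D4:**
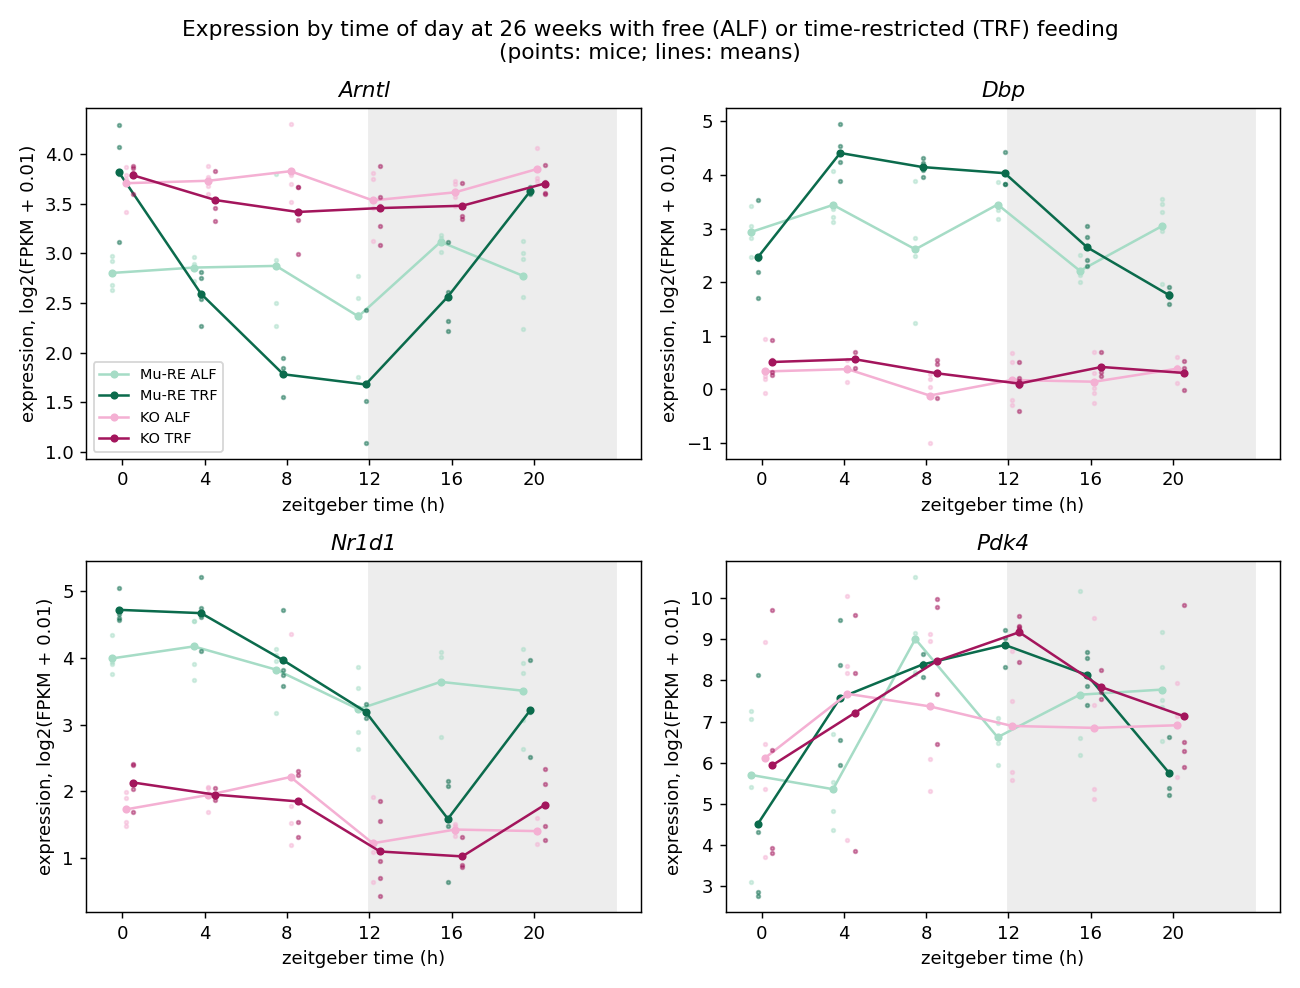
Log2 levels of Arntl, Dbp, Nr1d1 and Pdk4 by zeitgeber time (hours) in Mu-RE and KO mice of 26 weeks on ALF and TRF, with a point per mouse, lines through the means and grey for ZT 12 to 24. Arntl in Mu-RE muscle went from an amplitude of 0.10 on ALF to 1.15 on TRF, and was 0.18 in KO muscle on TRF.

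In old muscle time-restricted feeding raised Scd1, Fasn and Acly. Scd1 rose by 1.30 (SE 0.25, adjusted p = 0.0115), Fasn by 0.98 (SE 0.16) and Acly, which supplies acetyl-CoA for fat, by 0.35 (SE 0.07). Of 12 lipid synthesis genes, 3 rose (8 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 2e-08, adjusted p = 0.00134 with an estimated correlation). Of 12 endothelial and mural markers, 1 rose (11 adjusted over the list alone), with Pecam1 at 0.34 (SE 0.08) (camera adjusted p = 7.15e-10, adjusted p = 0.0623 with an estimated correlation). In all, 12 genes were higher and 2 lower, and 0 to 88 differed when 1 animal per time point was left out in turn. Rhythm was called for 563 genes on TRF and 139 on ALF, with 1873 and 1188 at an unadjusted p under 0.05, and Arrdc2 cycled 14.7-fold, Per1 10.7-fold and Arntl 7.41-fold. Limma called a difference in rhythm for 0 genes, with 915 at an unadjusted p under 0.05. Mean amplitude along the WT peak time rose from 0.17 (SE 0.02, n = 24) to 0.23 (SE 0.02, n = 24), a difference of 0.06 (SE 0.03, permutation p = 0.0214, adjusted p = 0.0385) that was lost in 2 of 4 fits with 1 animal per time point left out (largest p = 0.165).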

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

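The amplitude along the WT peak time, the length covariate, RE-RE against Br-RE mice and the tests of centring and of a few genes taking most reads were chosen after the result was seen. The last of these replaced the share of higher genes, which library scaling holds near even. The interactions stand here because the difference between groups was itself tested and called. The muscle by brain interaction at 10 weeks was called for 2 genes in level, Cyyr1 and Nctc1, and for 2 in rhythm, Nr1d1 and Leo1. As an amplitude along the WT peak time it was 0.11. The feeding by genotype interaction was called for 6 genes in level, among them Pdcd4 and Olfm1, and for 2 in rhythm, Arntl and D10Wsu102e. As an amplitude it was 0.17.

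Br-RE muscle at 10 weeks had 2862 called rhythms, but 164 with the length slope of each library as a covariate. Length bias between libraries may account for most. A biological daily change in RNA stays open there, since the design does not separate it from handling by time of day. WT mice on TRF had 4310 called rhythms with that covariate (3732 without) and 3965 genes differing in level from ALF (4043 without). This argues against bias along that slope, not other length effects. Genes peaking at ZT 0 to 4 were longer (median 5864.5 bp) than at ZT 12 to 16 (3711 bp). A fall of mitochondrial transcripts would scale all other genes of a library by 1 factor. Against it, 3489 of the 4043 were still called after quantile normalization, which removes that factor. Feeding time stays open for the WT response.

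Levels of Br-RE and RE-RE muscle against KO and WT mice could carry a shift from centring. If RE-RE mice equalled Mu-RE mice in level, centring alone would give the knockout score of Br-RE mice a difference of -0.26 from KO mice at 26 weeks, and -0.23 was observed (SE 0.05). If RE-RE mice equalled WT mice it would give -0.000982, and the first assumption was added after this one had argued against centring. At 10 weeks the slope of RE-RE minus WT on WT minus KO of 26 weeks was 0.00568 over 1334 genes, where 0.069 would be given if Br-RE equalled KO and RE-RE equalled WT mice, and the slope of Br-RE minus KO was 0.142. Both tests rest on assumed levels of the centred groups, so centring and an effect of brain Bmal1 on these levels cannot be told apart.

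The lower matrix genes of old mice may reflect bone or periosteal tissue in the younger samples, since 9 of the 22 were called lower with a bone marker mean as a covariate. The marker list was written before this test but after bone genes were seen among the lower genes. Its mean log2 was 3.46 (SD 1.11, n = 23) in WT mice of 10 weeks, 1.41 (SD 1.66, n = 22) at 26 weeks and -1.05 (SD 1.27, n = 24) in old mice, and of its 12 genes 5 passed the filter and 4 were lower in old mice (Acp5, Ctsk, Ibsp and Mmp13). With the covariate Col1a1 fell by 1.39 (SE 0.27, adjusted p = 0.000965) rather than 2.47 (SE 0.26). Age stays open for all 22, since the covariate is itself related to age.

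The calls were set against 100 splits of the same samples, the real one included, with time points permuted within a group or labels permuted within time points. In brackets stand the real count and the highest of the other splits. The shares were not adjusted for the number of counts tested. Rhythmic genes were as many in 1 of 100 splits for WT at 10 weeks (576, 4), WT at 26 weeks (103, 5), Mu-RE at 10 weeks (7, 1), Br-RE at 10 weeks (2862, 540), Br-RE at 26 weeks (68, 1), WT on TRF (3732, 4), Mu-RE on TRF (687, 1), KO on TRF (611, 1), old on ALF (139, 10) and old on TRF (563, 2), so no other split reached these counts. Rhythmic genes were as many in 2 of 100 splits for RE-RE at 10 weeks (58, 606) and RE-RE at 26 weeks (75, 93). Another split called more, so this unadjusted share does not by itself exclude chance for these counts. Rhythmic genes were as many in 3 of 100 splits for KO at 10 weeks (7, 1347), which does not by itself exclude chance for this count. A real count of 0 is reached by any split, here 100 of 100, so the splits say nothing on rhythmic genes in Mu-RE at 26 weeks (0, 1) and KO at 26 weeks (0, 541). Genes differing in level were as many in 1 of 100 splits for KO against WT at 10 weeks (4127, 1306), Mu-RE against KO at 10 weeks (3410, 8), RE-RE against KO at 10 weeks (3223, 668), RE-RE against WT at 10 weeks (402, 1), KO against WT at 26 weeks (4571, 0), Mu-RE against KO at 26 weeks (3341, 1885), Br-RE against KO at 26 weeks (111, 3), RE-RE against KO at 26 weeks (3753, 379), old against WT mice of 26 weeks (2383, 31), TRF against ALF in WT (4043, 1), TRF against ALF in Mu-RE (1669, 604), TRF against ALF in KO (1396, 0), TRF against ALF in old mice (14, 0), RE-RE against Br-RE at 10 weeks (3175, 437) and RE-RE against Br-RE at 26 weeks (3482, 3), so no other split reached these counts. Genes differing in level were as many in 2 of 100 splits for Br-RE against KO at 10 weeks (51, 3377), the muscle by brain interaction at 10 weeks (2, 4) and the feeding by genotype interaction (6, 145). This does not by itself exclude chance for these counts. For both interactions, in level and in rhythm, the labels of all groups were exchanged. Such splits remove the single effects as well, so they cannot decide on chance for an interaction. Genes differing in rhythm were as many in 1 of 100 splits for KO against WT at 10 weeks (51, 6), Br-RE against KO at 10 weeks (90, 61), TRF against ALF in Mu-RE (479, 5) and RE-RE against Br-RE at 10 weeks (15, 5), so no other split reached these counts. Genes differing in rhythm were as many in 2 of 100 splits for TRF against ALF in WT (387, 1252) and RE-RE against Br-RE at 26 weeks (9, 635), which does not by itself exclude chance for these counts. Genes differing in rhythm were as many in 3 of 100 splits for RE-RE against KO at 10 weeks (15, 2131), KO against WT at 26 weeks (17, 445) and the feeding by genotype interaction (2, 399). This does not by itself exclude chance for these counts. Genes differing in rhythm were as many in 4 of 100 splits for the muscle by brain interaction at 10 weeks (2, 1464), which does not exclude chance for this count. A real count of 0 is reached by any split, here 100 of 100, so the splits say nothing on genes differing in rhythm in Mu-RE against KO at 10 weeks (0, 1), RE-RE against WT at 10 weeks (0, 85), old against WT mice of 26 weeks (0, 0), TRF against ALF in KO (0, 0) and TRF against ALF in old mice (0, 3). Some splits called several times the real count, which points to a structure of the samples beyond the groups: for rhythm in RE-RE and KO mice at 10 weeks and KO mice at 26 weeks, for level in Br-RE against KO mice at 10 weeks and in the feeding by genotype interaction, and for differences in rhythm in RE-RE against KO and RE-RE against WT mice at 10 weeks, KO against WT mice at 26 weeks, TRF against ALF in WT mice, both interactions and RE-RE against Br-RE mice at 26 weeks. The sources used here give no batch for these splits.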

How the results depend on the processing

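The length covariate, the fits without KO 26 week replicate 11 or WT 10 week replicate 1, RE-RE against Br-RE and the amplitude along the WT peak time were chosen after the data were seen. Counts are called genes, each given as its value and the value under the alternative. The cause of these changes was not tested.

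With the length slope as a covariate, the number of genes differing in level changed in Br-RE against KO at 10 weeks (51 to 77), Br-RE against KO at 26 weeks (111 to 256), TRF against ALF in Mu-RE (1669 to 594), the muscle by brain interaction at 10 weeks (2 to 0) and the feeding by genotype interaction (6 to 21). The number differing in rhythm with this setting changed in Br-RE against KO at 10 weeks (90 to 0), RE-RE against KO at 10 weeks (15 to 25) and the muscle by brain interaction at 10 weeks (2 to 0). The number of rhythmic genes with this setting changed in Mu-RE at 10 weeks (7 to 15), Br-RE at 10 weeks (2862 to 164), RE-RE at 10 weeks (58 to 97), RE-RE at 26 weeks (75 to 117), KO at 10 weeks (7 to 13), KO on TRF (611 to 1358), old on ALF (139 to 210) and old on TRF (563 to 933). The amplitude along the WT peak time of Br-RE against KO at 10 weeks went from 0.0154 to 0.0464 (p = 0.0345). The amplitude along the WT peak time of the muscle by brain interaction at 10 weeks went from 0.1103 to 0.0620 (p = 0.0773). The amplitude along the WT peak time of the muscle by brain interaction at 26 weeks went from 0.0694 to 0.0794 (p = 0.0451).

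Without the filter on low values, the number of genes differing in level changed in TRF against ALF in old mice (14 to 7), the muscle by brain interaction at 10 weeks (2 to 1) and the feeding by genotype interaction (6 to 3). The number differing in rhythm with this setting changed in Br-RE against KO at 10 weeks (90 to 51) and RE-RE against WT at 10 weeks (0 to 2). The number of rhythmic genes with this setting changed in KO on TRF (611 to 361). The knockout score of TRF against ALF in KO went from 0.111 to 0.0683 (p = 0.198).

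In 1 fit over all 15 groups, the number of genes differing in level changed in Br-RE against KO at 10 weeks (51 to 25), TRF against ALF in KO (1396 to 2749), TRF against ALF in old mice (14 to 52), the muscle by brain interaction at 10 weeks (2 to 0) and the feeding by genotype interaction (6 to 153). The number differing in rhythm with this setting changed in Br-RE against KO at 10 weeks (90 to 20), RE-RE against WT at 10 weeks (0 to 2), KO against WT at 26 weeks (17 to 33), TRF against ALF in KO (0 to 183), TRF against ALF in old mice (0 to 1), the feeding by genotype interaction (2 to 7) and RE-RE against Br-RE at 10 weeks (15 to 149). The number of rhythmic genes with this setting changed in WT at 26 weeks (103 to 164), Mu-RE at 26 weeks (0 to 5), Br-RE at 10 weeks (2862 to 1452), Br-RE at 26 weeks (68 to 43), RE-RE at 10 weeks (58 to 129), RE-RE at 26 weeks (75 to 400), KO at 10 weeks (7 to 17), KO at 26 weeks (0 to 23), KO on TRF (611 to 3685) and old on ALF (139 to 288).

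With a pseudocount of 1 FPKM, the number of genes differing in level changed in the muscle by brain interaction at 10 weeks (2 to 5). The ageing score of RE-RE against Br-RE at 26 weeks went from 0.154 to 0.0903 (p = 0.186).

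After quantile normalization, the number of genes differing in level changed in the muscle by brain interaction at 10 weeks (2 to 11). The number differing in rhythm with this setting changed in Br-RE against KO at 10 weeks (90 to 140), TRF against ALF in WT (387 to 669) and TRF against ALF in old mice (0 to 1).

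With the label number as a block, the number of genes differing in level changed in Br-RE against KO at 10 weeks (51 to 24), the muscle by brain interaction at 10 weeks (2 to 10) and the feeding by genotype interaction (6 to 28). The number differing in rhythm with this setting changed in KO against WT at 10 weeks (51 to 31), Br-RE against KO at 10 weeks (90 to 42), RE-RE against KO at 10 weeks (15 to 9), KO against WT at 26 weeks (17 to 4), TRF against ALF in WT (387 to 2), TRF against ALF in Mu-RE (479 to 133), RE-RE against Br-RE at 10 weeks (15 to 9) and RE-RE against Br-RE at 26 weeks (9 to 4).

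With time as a factor, the number differing in rhythm changed in KO against WT at 10 weeks (51 to 25), Br-RE against KO at 10 weeks (90 to 10), RE-RE against WT at 10 weeks (0 to 4), KO against WT at 26 weeks (17 to 4), old against WT mice of 26 weeks (0 to 1), TRF against ALF in WT (387 to 22), TRF against ALF in Mu-RE (479 to 2441), the feeding by genotype interaction (2 to 11) and RE-RE against Br-RE at 10 weeks (15 to 43). The number of rhythmic genes with this setting changed in WT at 26 weeks (103 to 66), Mu-RE at 26 weeks (0 to 29), Br-RE at 10 weeks (2862 to 1709), Br-RE at 26 weeks (68 to 6), KO at 10 weeks (7 to 14), KO at 26 weeks (0 to 2), WT on TRF (3732 to 2433), Mu-RE on TRF (687 to 2034), KO on TRF (611 to 113) and old on TRF (563 to 317).

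Leaving out 1 animal of each time point in turn, or KO 26 week replicate 11 where that library took part, gave the ranges in brackets. The number of genes differing in level ranged widely in Br-RE against KO at 10 weeks (3 to 44), RE-RE against WT at 10 weeks (138 to 362), Br-RE against KO at 26 weeks (15 to 154), old against WT mice of 26 weeks (1040 to 3019), TRF against ALF in WT (1976 to 3577), TRF against ALF in Mu-RE (275 to 1142), TRF against ALF in KO (90 to 1504), TRF against ALF in old mice (0 to 88), the muscle by brain interaction at 10 weeks (0 to 44) and the feeding by genotype interaction (0 to 3). Genes differing in rhythm did so in KO against WT at 10 weeks (10 to 44), Br-RE against KO at 10 weeks (0 to 310), RE-RE against KO at 10 weeks (4 to 10), KO against WT at 26 weeks (1 to 32), TRF against ALF in WT (0 to 540), TRF against ALF in Mu-RE (20 to 1307), TRF against ALF in old mice (0 to 1), the muscle by brain interaction at 10 weeks (0 to 126), the feeding by genotype interaction (0 to 3), RE-RE against Br-RE at 10 weeks (4 to 15) and RE-RE against Br-RE at 26 weeks (2 to 8). Rhythmic genes did so in WT at 10 weeks (184 to 278), WT at 26 weeks (30 to 49), Mu-RE at 10 weeks (1 to 3), Br-RE at 10 weeks (533 to 2850), Br-RE at 26 weeks (5 to 74), RE-RE at 10 weeks (12 to 40), RE-RE at 26 weeks (19 to 44), KO at 10 weeks (0 to 3), WT on TRF (1938 to 3091), Mu-RE on TRF (134 to 529), KO on TRF (1 to 75), old on ALF (44 to 62) and old on TRF (155 to 371). Tests changed their call for the knockout score of TRF against ALF in KO (0.0834 to 0.137), knockout score of TRF against ALF in old mice (0.0213 to 0.1002), ageing score of RE-RE against KO at 26 weeks (0.154 to 0.306), ageing score of TRF against ALF in KO (0.0389 to 0.199), ageing score of RE-RE against Br-RE at 26 weeks (0.0787 to 0.191), amplitude of Br-RE against KO at 26 weeks (0.0790 to 0.0958) and amplitude of TRF against ALF in old mice (0.0452 to 0.0848).

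Without KO 26 week replicate 11 alone, the rhythm of 32 genes differed between KO and WT mice at 26 weeks, against 17 with it, and 3 genes had a feeding by genotype interaction in level, against 6. Without WT 10 week replicate 1, 4066 genes differed in level between KO and WT mice at 10 weeks, against 4127, and 46 in rhythm, against 51, while 342 differed in level between RE-RE and WT mice, against 402, and 499 were rhythmic in WT mice, against 576. The sources used here do not say whether numbers in the sample labels pair mice across groups. Deviations of libraries sharing a number correlated at a mean r of 0.0406 over 2353 pairs and others at -0.0126 over 7278 pairs. Of the pairs sharing a number, 36.7% were above 0.1. The difference was not tested and does not settle whether the numbers pair mice, so the block on them is an alternative. Leaving out 1 animal per time point lowers the number of mice per time point to about 3, so lower counts reflect smaller samples as well as single mice. Depth limits genes near 1 FPKM, where 93.7 reads carry counting noise. Over these results, 574 values under an alternative stayed on the same side of their threshold or within 1.5 times of their count, 190 counts moved, 12 tests were weaker and 4 stronger. Over the named genes and all alternatives, 18234 tests kept their call, 1096 were weaker and 234 stronger.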

Other observations

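The overlaps and library checks in this part were chosen after the data were seen. Rhythmic genes were set against those of WT mice at 10 weeks. Old mice on ALF shared 86 of 139 (8.12 expected for independent lists), and WT mice of 26 weeks 78 of 103 (6.02 expected). KO mice on TRF shared 61 of 611 (35.7 expected), and 400 with WT mice on TRF (231 expected). Shared genes peaked a median of 0.933 h apart in WT mice at 26 and 10 weeks, and 0.95 h in KO and WT mice on TRF.

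KO 26 week replicate 11, taken at ZT 8, had glucocorticoid-responsive genes 3.34 and atrophy genes 1.91 above its group on the log2 scale, and a knockout score of 0.20 where its group had a mean of 0.87 (SD 0.18, n = 24). Other outlying libraries were RE-RE 26 week replicate 22 in denervation genes (1.97), RE-RE 26 week replicate 1 in slow fibre genes (-2.13), WT 10 week replicate 1 in heat shock genes (1.48) and old TRF replicate 20 in red blood cell genes (3.79), whose reads are shared between paralogs. Stress before death and a mixed sample were not tested as sources.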
